A study of Homo sapiens with 4 samples.

How the data were processed

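Total RNA from A549 cells, an established human lung carcinoma epithelial line, was sequenced in 4 libraries. Per the labels, the cells had been transfected for 24 hr with 1 µg of either the empty expression plasmid pCMV6-Entry (2 libraries) or a plasmid encoding SAMD9 with a Myc-DDK tag (2 libraries), RNA was extracted with Trizol, and ribosomal RNA was depleted with the KAPA RiboErase kit. Groups and replicate numbers were taken from the sample titles. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

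Each deposited file gave 1 library's raw counts per gene, with CPM and RPKM values that the authors had computed from them. The deposited CPM values equalled the counts scaled by the library total, and the deposited RPKM values equalled CPM per kilobase of the listed gene length, so neither was used in a test. Per the submitters' processing notes, the tools were bcl2fastq, STAR 2.5.1a and featureCounts 1.4.6-p5 of Subread, with the genome build GRCh38. Their parameters, the annotation release and the strand setting are not given in the sources used here. Reads of a gene and of a gene overlapping it on the other strand are therefore treated as inseparable. Among counts from 1 to 20, 72.9% were even, against 49.7% of counts above 1000, as when both mates of a read pair are counted, so intervals on low counts are too narrow if that is the case.

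The files listed 58812 Ensembl genes, of which 22639 had a count of 0 in all 4 libraries. Of the gene IDs, 55297 were found in GENCODE release 29, and 51535 of these had the same start and end there. Symbols came from a table of gene names (54836 IDs) and otherwise from GENCODE. Coordinates are those of the files. Library totals were 29301854 and 31434339 counts for the empty vector and 39670083 and 30750029 for SAMD9. A single count was worth between 0.0252 and 0.0341 CPM. The 10 most abundant genes took between 5.97% and 6.26% of a library. The replicates of each group were compared before use: the chi-square statistic per degree of freedom over genes with at least 20 counts in the pair was 9.44 between the empty vector libraries and 5.02 between the SAMD9 libraries, so neither pair was a library deposited more than once.

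Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (minimum count 10, minimum total count 15), which left 19814 genes holding at least 99.9% of each library's counts. Normalisation was by TMM, with factors of 1.07 and 1.07 for the empty vector and 0.941 and 0.932 for SAMD9. Dispersions were estimated and a quasi-likelihood F-test (glmQLFit and glmQLFTest, defaults of the installed version) compared the groups with no covariate. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Standard errors (SE) of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F. Expression levels are TMM-normalised CPM, as mean ± SD over n = 2 libraries. With 2 libraries against 2, an exact permutation test of a single gene cannot give a two-sided p below 0.333, so significance rests on the spread shared across genes by edgeR.

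The design, the alternatives, 27 gene lists and the rule for named genes were fixed before the data were examined. The rule names SAMD9 and its paralog SAMD9L, the 10 largest rises and 10 largest falls among called genes with an average log2 CPM of at least 1, both SAMD9 libraries on the same side of both empty vector libraries and a symbol that is not a clone name, and of each list the 3 members with the lowest p (4 where the list's test passed). Some genes that the rule names are not reported here. The pattern that recognises clone names was written after a first look at the data. The lists cover type I interferon-stimulated genes, interferon ligands, interferon-gamma-type genes, MHC class I antigen presentation, NF-kB and inflammatory cytokines, nucleic acid sensing, the integrated stress response, the unfolded protein response, immediate early genes, p53 targets, cell death, mitosis, DNA replication, histones, cholesterol synthesis, NRF2 targets, heat shock, ribosomal proteins, aminoacyl-tRNA synthetases, mitochondrial mRNAs, structured non-coding RNAs, hypoxia, TGF-beta and matrix, and markers of lung epithelium, fibroblasts, leukocytes and endothelium. Lists with at least 3 tested members (26) were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided), adjusted over these lists. Camera was repeated with a correlation estimated from the data, and fry was run beside it. With so few libraries, that correlation and the test that uses it rest on few degrees of freedom. A call lost there does not show that a list did not move.

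For a gene with a count of 0 in both libraries of a group, the fold is a lower bound against 3 counts over the group. For a gene with 1 to 3 counts in a group, the ratio of counts is given with its exact (Clopper-Pearson) 95% interval. Bounds and intervals cover counting error only. Named genes were checked for 31-mers of GENCODE 29 transcripts shared with other genes, and for overlapping exons in the exon coordinates deposited with the counts. The alternatives were other scalings, DESeq2 1.42.0, a robust fit, no and stricter filters (50 counts in 2 libraries), the replicate number as a block, SAMD9 removed, each library left out in turn, a fold threshold, other list tests and, chosen after seeing the data, the non-legacy fit and counts halved. The procedure was tested on counts simulated for this comparison (18832 genes after filtering, 200 changed before filtering): 45.8% of genes changed by 0.5 on the log2 scale were recovered, 68.8% at 1, 83.3% at 2 and 97.9% at 4, 4.7% of calls were false, and 0 of 26 random lists were called. Genes were simulated independently, so the random lists did not test list calls under correlation between genes. Only 200 genes were changed, while 27.5% of genes were called in the data, so the simulated shares need not carry over. Other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.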

Results

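Gene expression was measured by RNA sequencing in A549 lung carcinoma cells 24 hr after transfection with the empty plasmid pCMV6-Entry (n = 2 libraries) or with a plasmid encoding tagged SAMD9 (n = 2 libraries). Library totals ranged from 29301854 to 39670083 counts. The only comparison the design names is SAMD9 against empty vector, which asks how the transcriptome responds to SAMD9 overexpression. SAMD9 is an interferon-inducible protein with antiviral activity.

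SAMD9 itself (ENSG00000205413, chromosome 7, 93099513 to 93118023, minus strand, GRCh38) had 444 and 400 counts in the empty vector libraries and 220123 and 184350 in the SAMD9 libraries. Its level was 13.1 ± 1.58 CPM (SD, n = 2) with empty vector and 6171 ± 379 CPM (SD, n = 2) with SAMD9, a log2 fold change of 8.88 (SE 0.08, edgeR adjusted p = 2.2e-26). Gene counts do not separate reads of the plasmid from reads of the endogenous gene. SAMD9L, the neighbouring paralog (ENSG00000177409, chromosome 7, 93130055 to 93148369), rose from 3.47 ± 1.69 to 353 ± 19.0 CPM (SD, n = 2), a log2 fold change of 6.68 (SE 0.14, adjusted p = 1.7e-20). Only 0.029% of SAMD9's transcript 31-mers also occur in SAMD9L.

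With SAMD9, all 44 type I interferon-stimulated genes, 18 of 19 interferon-gamma-type genes and all 17 genes of MHC class I antigen presentation rose, whereas 23 of 26 mitotic genes and 39 of 61 histone genes fell. The 5 lists passed camera, but with an estimated correlation the calls were lost for antigen presentation (adjusted p = 0.0739), mitotic genes and histones (adjusted p = 0.710 for each). That repeat had few degrees of freedom, so a lost call does not show that a list did not move. Of 19814 genes tested, 3038 were higher and 2420 lower with SAMD9 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), which is 27.5% of genes. An absolute log2 fold change of at least 1 was reached by 1202 of the higher genes and 288 of the lower ones, and 138 genes rose by at least 5 on the log2 scale. At that threshold of 1, 1030 were higher and 621 lower under total-count scaling, and 1018 and 159 with DESeq2. Scaling by total counts in place of TMM shifted the median gene by -0.19 on the log2 scale and gave 1974 higher and 5653 lower genes, so that 25.9% of calls were higher, against 55.7% with TMM. Without SAMD9 replicate 2, 1466 genes were lower.

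**Figure D1:**
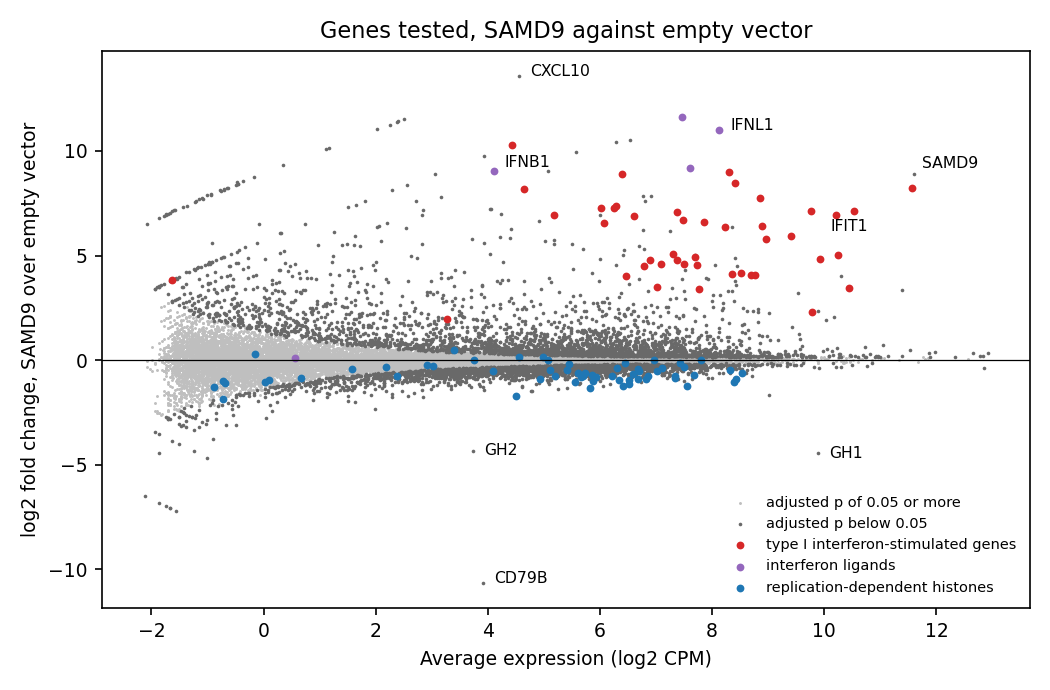
Log2 fold change (SAMD9 over empty vector) against average expression in log2 CPM, 1 point per tested gene (19814), with 3 gene lists coloured. The 44 type I interferon-stimulated genes lie above 0, and GH1, GH2 and CD79B lie lowest among the labelled genes. Points of genes with a count of 0 in a group, such as CXCL10, are fitted values that depend on the prior count.

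Interferon ligands were among the largest rises. Of the 5 ligand genes tested, IFNB1, IFNL1, IFNL2 and IFNL3 rose (4 also when adjusted over the list alone), and IFNE had a log2 fold change of 0.12 (SE 0.39, adjusted p = 0.87). IFNA1, IFNA2, IFNG and IFNK had too few counts to test. IFNB1, the interferon beta gene, went from 2 and 2 counts to 1094 and 1124, or 34.3 ± 7.02 CPM (SD, n = 2), a log2 fold change of 9.03 (SE 0.29). The interferon lambda genes on chromosome 19 reached 555 ± 104 CPM for IFNL1, 354 ± 53.3 for IFNL2 and 390.5 ± 56.8 for IFNL3 (SD, n = 2), with log2 fold changes of 11.02 (SE 0.20), 11.63 (SE 0.18) and 9.19 (SE 0.14). IFNL2 and IFNL3 share 53.9% and 51.6% of their transcript 31-mers with each other, so the division of counts between them is uncertain. IFNL4, annotated there as a polymorphic pseudogene, had 0 counts with empty vector and 618 with SAMD9, at least 202-fold higher. The list passed camera (adjusted p = 5.5e-56), and with an estimated correlation the adjusted p was 0.0433.

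All 44 type I interferon-stimulated genes rose (44 adjusted over the list alone), with a median log2 fold change of 5.86. With DESeq2, and without empty vector replicate 2, SAMD9 replicate 1 or SAMD9 replicate 2, 43 of the 44 did. Their share of all counts was 0.126% and 0.12% in the empty vector libraries and 3.23% and 3.47% in the SAMD9 libraries. The antiviral effector RSAD2 rose 516-fold (log2 fold change 9.01, SE 0.11), IFIT1, which binds viral RNA ends, 122-fold (6.93, SE 0.08), IFI6 60.6-fold (5.92, SE 0.07) and the RNA sensor RIGI 56-fold (5.81, SE 0.07). The edgeR adjusted p was 2.0e-24 for each of these 4 genes. The list's camera p is too small for the software to print, and the adjusted p was 0.0433 with an estimated correlation. RSAD2 overlaps CMPK2, which also rose, over 14 exonic bases on the opposite strand.

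Genes typical of the interferon-gamma response rose in 18 of 19 cases (18 adjusted over the list alone; median 5.46). The T cell chemoattractant CXCL10 had no counts with empty vector and 1358 and 1649 with SAMD9, at least 985-fold higher. GBP1 rose by 7.59 (SE 0.13), the transcription factor IRF1 by 4.48 (SE 0.07), APOL6 by 4.90 (SE 0.07) and APOL2 by 4.55 (SE 0.07) on the log2 scale. GBP4 rose by 10.50 (SE 0.19), and GBP5 was at least 172-fold higher from 0 counts. The pseudogene GBP1P1 was at least 222-fold higher, with 22.4% of its 31-mers shared with GBP1. CD74 did not pass, at 0.70 (SE 0.47, adjusted p = 0.30). The camera adjusted p was 5.9e-140, and 0.0433 with an estimated correlation.

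All 17 genes of MHC class I antigen presentation rose (17 adjusted over the list alone; median 3.31). NLRC5, the transactivator of these genes, rose 32.1-fold, the peptide transporter gene TAP1 13.8-fold, HLA-C 11.98-fold and HLA-E 9.93-fold, with SE from 0.07 to 0.08 on the log2 scale. HLA-C shares 343 exonic bases with HLA-B in the exon coordinates deposited with the counts. Camera gave an adjusted p of 4.0e-125, but the call was lost with an estimated correlation (adjusted p = 0.0739).

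Nucleic acid sensing genes rose in 15 of 18 cases (16 adjusted over the list alone; median 2.71). Some genes are in more than 1 list, such as RIGI in this list and the type I interferon-stimulated list, so the list calls are not independent. IFIH1, the gene of the RNA sensor MDA5, rose by 6.62 (SE 0.09), IFI16 by 5.32 (SE 0.09) and ZC3HAV1, the zinc finger antiviral protein gene, by 4.01 (SE 0.06) on the log2 scale. ZBP1 went from 0 counts to 424 and 317, at least 243-fold higher. Camera gave adjusted p = 9.8e-86, and 0.0433 with an estimated correlation. Under total-count scaling, and without empty vector replicate 1, 1 member of that list was lower. Of the NF-kB and inflammatory cytokine genes, 26 of 28 rose and 1, IL11, named after its value was seen, fell (the same numbers adjusted over the list alone; median 2.11). No member was lower with DESeq2 or without empty vector replicate 1, SAMD9 replicate 1 or SAMD9 replicate 2. The chemokine gene CCL5 rose by 10.44 (SE 0.24) from 3 and 4 counts to 4820 and 5228. The NF-kB inhibitors TNFAIP3 and NFKBIA rose by 3.93 (SE 0.10) and 2.73 (SE 0.07), and SOD2 by 2.42 (SE 0.07), although SOD2 overlaps WTAP and ACAT2 on the opposite strand. The list's camera adjusted p was 2.7e-46, with the call lost under an estimated correlation (adjusted p = 0.112).

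Cell death genes rose in 15 of 20 cases and fell in 2 (15 and 4 adjusted over the list alone; median 1.30). TNFSF10, which encodes the death ligand TRAIL, went from 1.03 ± 0.617 to 239 ± 12.8 CPM (SD, n = 2). PMAIP1, which encodes the BH3-only protein NOXA, rose by 2.66 (SE 0.10) and the necroptosis gene MLKL by 2.15 (SE 0.07) on the log2 scale. The list members RIPK3 (0 and 0 counts with empty vector, 2 and 0 with SAMD9) and BCL2A1 had too few counts to test. The 2 that fell were BCL2 (-0.82, SE 0.20) and BCL2L1 (-0.23, SE 0.06), named after their values were seen. Without SAMD9 replicate 2, 1 member was lower, and 4 were under total-count scaling. Camera gave adjusted p = 1.5e-25, and 0.0433 with an estimated correlation.

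Among immediate early genes, 14 of 25 rose and 2 fell (14 and 3 adjusted over the list alone; median 0.44). KLF4 rose by 2.56 (SE 0.09), ZFP36, which promotes decay of cytokine mRNAs, by 2.51 (SE 0.07), KLF6 by 1.81 (SE 0.06) and JUN by 1.68 (SE 0.06). Camera gave adjusted p = 3.4e-09, and the call was lost with an estimated correlation (adjusted p = 0.0985). The falls numbered 5 under total-count scaling, 0 with DESeq2 or without empty vector replicate 1 or SAMD9 replicate 1, and 1 without SAMD9 replicate 2, without a filter or with the replicate number as a block. Heat shock genes rose in 10 of 18 cases and fell in 1 (11 and 1 adjusted over the list alone), with a median of 0.18 that became -0.01 under total-count scaling, where 4 rose and 5 fell. Without SAMD9 replicate 2, 4 rose. HSPA6 rose by 2.22 (SE 0.19), the co-chaperone DNAJA1 by 1.19 (SE 0.06), HSPA1B by 0.94 (SE 0.07) and HSPA1A by 0.81 (SE 0.07). HSPA1A and HSPA1B share 73.6% and 73.1% of their 31-mers with each other, and HSPA6 shares 56.6% with HSPA7, so their separate values are uncertain. The list's camera adjusted p was 0.0472, 0.289 under total-count scaling and 0.784 with an estimated correlation, and the call also ended without empty vector replicate 1 (0.052), SAMD9 replicate 1 (0.0584) or SAMD9 replicate 2 (0.0609).

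**Figure D2:**
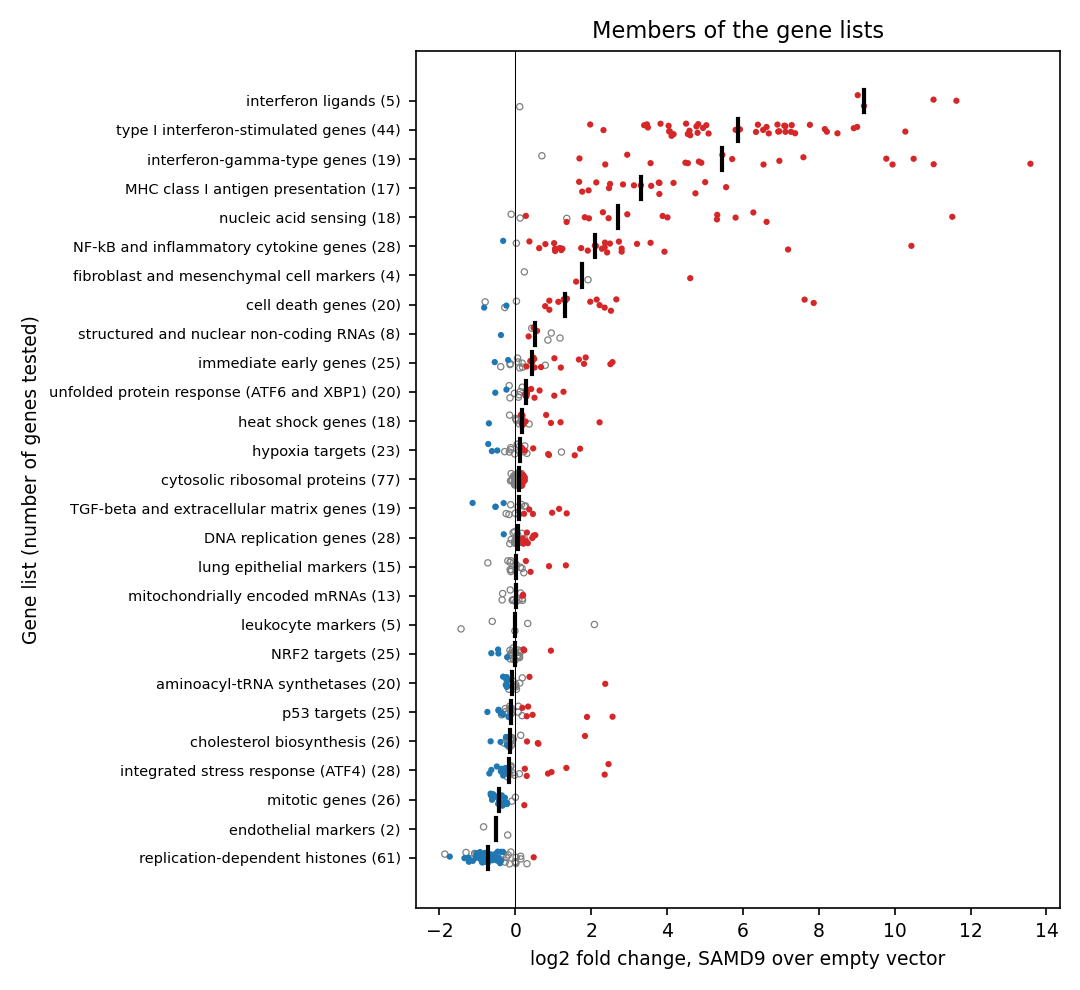
Log2 fold change (SAMD9 over empty vector) of the tested members of the 27 lists, 1 point per gene. Red and blue points passed with a rise or fall, open grey points did not pass, and black bars are list medians, from 9.19 for interferon ligands to -0.72 for histones.

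Mitotic genes fell in 23 of 26 cases and 1, BUB1, named after its value was seen, rose (23 and 1 adjusted over the list alone; median -0.43). The DNA topoisomerase gene TOP2A fell from 471.5 ± 30.0 to 311 ± 10.7 CPM (SD, n = 2), CENPF had a log2 fold change of -0.63 (SE 0.06), KIF23 of -0.58 (SE 0.06) and the mitotic kinase gene PLK1 of -0.58 (SE 0.07). Of 61 replication-dependent histone genes, which supply histones in S phase, 39 fell and 1 rose (42 and 1 adjusted over the list alone; median -0.72). H1-3 fell from 264 ± 21.0 to 113 ± 9.30 CPM (SD, n = 2), and H4C4, H4C3 and H4C8 had log2 fold changes of -1.22 (SE 0.08), -1.12 (SE 0.08) and -0.93 (SE 0.07). Camera gave adjusted p = 1.1e-06 for mitotic genes and 1.5e-14 for histones, and both calls were lost with an estimated correlation (adjusted p = 0.710 for each). Neither list had a member called higher under total-count scaling, without empty vector replicate 1 or without SAMD9 replicate 1, nor had mitotic genes without SAMD9 replicate 2 or histones with DESeq2. Of the DNA replication genes, 9 of 28 rose and 1 fell (9 and 1 adjusted over the list alone), GINS1 by 0.53 (SE 0.07), CLSPN by 0.48 (SE 0.09) and PCNA by 0.45 (SE 0.06). That list was not called (camera adjusted p = 0.639), and its median went from 0.07 to -0.12 under total-count scaling, where 3 rose and 8 fell. Without SAMD9 replicate 2, 4 rose and 0 fell, and the count of falls was 2 without empty vector replicate 1 and 0 with DESeq2 or without either of the other libraries.

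The largest falls after the rule lay at the growth hormone locus on chromosome 17. GH1 (63917200 to 63918838), the pituitary growth hormone gene, went from 1810 ± 345 to 82.5 ± 4.57 CPM (SD, n = 2), a log2 fold change of -4.46 (SE 0.09, adjusted p = 1.4e-20), and GH2 had one of -4.32 (SE 0.18). CD79B (63928740 to 63932354), a B cell receptor component, had 1171 and 760 counts with empty vector and 0 and 1 with SAMD9, a ratio of 1966 with a counting interval from 352 to 77690. GH1 shares 62.4% of its transcript 31-mers with other genes. Of the 31-mers of GH1 55.3%, and of those of CD79B 12.3%, occur in 1 gene that GENCODE 29 annotates across both (ENSG00000285947). The deposited exon coordinates list no such gene overlapping GH1 or CD79B, so its expression was not measured. GH2 stayed at 1.403% of the GH1 count with empty vector and 1.535% with SAMD9, so these genes' separate values are uncertain. The other falls named by the rule were smaller: LINC00485 (-2.31, SE 0.27), MYRF-AS1 (-1.78, SE 0.33), INSYN2B (-1.76, SE 0.21), the glycogen-targeting subunit gene PPP1R3C (-1.74, SE 0.19), the histone gene H4C13 (-1.73, SE 0.16), GAS6-AS1 (-1.71, SE 0.21) and PKD1L2 (-1.71, SE 0.28). MYRF-AS1 overlaps DAGLA, and GAS6-AS1 overlaps GAS6, on the opposite strand. Of the rises named by the rule, RUFY4 belongs to none of the lists and was at least 224-fold higher, from 0 to 685 counts.

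**Figure D3:**
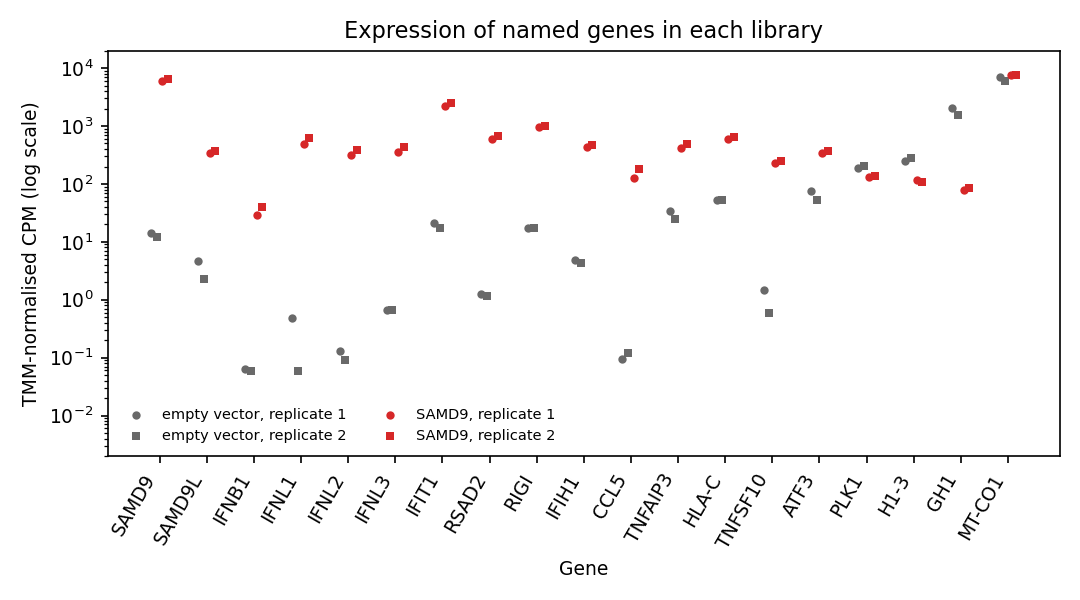
TMM-normalised CPM, on a log scale, of 19 named genes in each of the 4 libraries, 1 point per library. Both SAMD9 libraries lie above both empty vector libraries for each gene from SAMD9 to ATF3 and for MT-CO1, and below them for PLK1, H1-3 and GH1.

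Stress response lists were mixed. Of 28 integrated stress response genes, 7 rose and 12 fell (7 and 14 adjusted over the list alone; camera adjusted p = 0.927). ATF3 rose by 2.46 (SE 0.10), PPP1R15A by 2.36 (SE 0.09) and CEBPB by 0.86 (SE 0.06), whereas the list median was -0.16 and its mean 0.12. The falls numbered 19 under total-count scaling, 7 without empty vector replicate 1 and 6 without SAMD9 replicate 2. Unfolded protein response genes rose in 11 of 20 cases and fell in 2 (12 and 2 adjusted over the list alone; camera adjusted p = 0.115), and under total-count scaling 5 rose and 5 fell. The list was called higher with DESeq2 (adjusted p = 0.0262), without a filter (0.000141) and without empty vector replicate 1 (0.00151), and 4 members fell without empty vector replicate 2 and 1 without any other library. SEC24D rose by 1.27 (SE 0.10), XBP1 by 1.03 (SE 0.07) and HERPUD1 by 0.64 (SE 0.08). Among 25 p53 targets, 6 rose and 7 fell (6 and 9 adjusted over the list alone; camera adjusted p = 0.907; median -0.12, mean 0.06). The pro-apoptotic gene BBC3 rose by 2.56 (SE 0.08), the death receptor genes FAS and TNFRSF10B by 1.89 (SE 0.12) and 0.46 (SE 0.06). FAS overlaps ACTA2 on the opposite strand. Of these targets, 3 rose and 14 fell under total-count scaling, and 4 fell without SAMD9 replicate 2. NRF2 targets had 3 rises and 4 falls among 25 (3 and 4 adjusted over the list alone; camera adjusted p = 0.639), with HMOX1 at 0.94 (SE 0.07), the cystine transporter gene SLC7A11 at -0.63 (SE 0.06) and GCLC at -0.45 (SE 0.07). For NRF2 targets, 1 rose and 14 fell under total-count scaling, 8 rose without empty vector replicate 2, and the falls numbered 7 without empty vector replicate 1 and 2 without SAMD9 replicate 2. Of 23 hypoxia targets, 7 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.614), with HK2 at 1.71 (SE 0.18), ANGPTL4 at 1.57 (SE 0.14) and ADM at 0.87 (SE 0.07). Without empty vector replicate 2, 12 hypoxia targets rose, and fry, which asks whether genes move in a common direction on balance and not whether they move more than other genes, called that list higher (adjusted p = 0.0416).

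Lists of metabolism and translation were not called by camera either. Cholesterol synthesis had 4 rises and 4 falls among 26 genes (4 and 6 adjusted over the list alone; camera adjusted p = 0.781), with STARD4 at 1.84 (SE 0.09) and HMGCS1 at 0.59 (SE 0.06). Under total-count scaling 3 rose and 20 fell, and the falls numbered 7 without empty vector replicate 1, 2 without empty vector replicate 2 or with DESeq2, and 1 without SAMD9 replicate 2. Cytosolic ribosomal protein genes rose in 21 of 77 cases (21 adjusted over the list alone; camera adjusted p = 0.614), whereas 0 rose and 20 fell under total-count scaling, with medians of 0.10 and -0.09. The rises numbered 6 without SAMD9 replicate 1 and 1 without SAMD9 replicate 2, 1 member fell without empty vector replicate 2, and without a filter the list was called higher (adjusted p = 0.0106). RPS28 and RPS19 had log2 fold changes of 0.25 (SE 0.06) and 0.22 (SE 0.05), and neither passed under total-count scaling or without SAMD9 replicate 2 (adjusted p = 0.05305 and 0.0914). Of 20 aminoacyl-tRNA synthetase genes, 2 rose and 7 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.927; median -0.08, mean 0.04). WARS1, also an interferon-gamma-type gene, rose by 2.37 (SE 0.07), KARS1 by 0.37 (SE 0.06), and IARS1 fell by 0.32 (SE 0.06). The falls numbered 15 under total-count scaling, 4 without empty vector replicate 1, 2 without SAMD9 replicate 1 and 1 without SAMD9 replicate 2. Mitochondrial mRNAs gave 2 rises among 13 (1 adjusted over the list alone; camera adjusted p = 0.933, direction down, with a median of 0.02): MT-CO1 at 0.20 (SE 0.05) and MT-CO2 at 0.20 (SE 0.08), while MT-ND3 had 0.19 (SE 0.08, adjusted p = 0.0727). Neither MT-CO1 nor MT-CO2 passed under total-count scaling, MT-CO2 not without empty vector replicate 2, with DESeq2 (adjusted p = 0.566) or with a robust fit (0.486) either, and they share 66.7% and 50.5% of 31-mers with other genes. That list was called higher without empty vector replicate 1 (adjusted p = 0.0152) and lower without empty vector replicate 2 (0.0105), with 11 rises and 0 falls in the former and 1 rise and 7 falls in the latter. It had 0 rises and 5 falls under total-count scaling, 5 rises and 2 falls without a filter, and 2 falls without SAMD9 replicate 1. MT-ND3 passed without a filter (0.0403), with the stricter filter (0.0439), with halved counts (0.0473) and without empty vector replicate 1 (7.5e-06). Structured and nuclear non-coding RNAs gave 3 rises and 1 fall among 8 (3 and 1 adjusted over the list alone; camera adjusted p = 0.614), with NEAT1 at 0.58 (SE 0.07), RN7SL3 at 0.48 (SE 0.09) and RN7SL2 at 0.35 (SE 0.05). Fry called this list higher (adjusted p = 0.0105). RN7SL3 did not pass with DESeq2 or a robust fit, with 0 falls in the list under either, and 72.9% and 94.8% of the 31-mers of RN7SL3 and RN7SL2 occur in other genes.

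Matrix and cell type lists were not called by camera, while fry called the matrix list (adjusted p = 0.0423) and fibroblast markers (0.00327) higher. Under total-count scaling more members fell than rose in the hypoxia (6 and 5), matrix (8 and 5) and lung epithelial (4 and 3) lists. TGF-beta and extracellular matrix genes gave 6 rises and 4 falls among 19 (9 and 5 adjusted over the list alone; camera adjusted p = 0.614), with FN1 at 1.16 (SE 0.06) and TGFB2 at -1.12 (SE 0.07). Lung epithelial markers rose in 4 of 15 cases (4 adjusted over the list alone; camera adjusted p = 0.650), with MUC1 at 1.33 (SE 0.14), the E-cadherin gene CDH1 at 0.89 (SE 0.08) and KRT8 at 0.40 (SE 0.05). KRT8 overlaps KRT18 on the opposite strand. Without empty vector replicate 2, 7 of these markers rose, and 1 fell when either empty vector library or SAMD9 replicate 1 was left out. Fibroblast markers gave 2 rises among 4 (2 adjusted over the list alone; camera adjusted p = 0.497): COL1A1 at 1.60 (SE 0.25), and FAP, whose 2 and 56 counts give a ratio of 27.5 with a counting interval from 7.27 to 233. With the stricter filter 1 of 2 tested fibroblast markers rose. COL3A1 had 1.92 (SE 0.87, adjusted p = 0.111). Leukocyte markers gave 0 calls among 5 with edgeR, also when adjusted over the list alone (camera adjusted p = 0.927, direction down; median -0.01, mean 0.07). CD68 had 2.09 (SE 0.90), CSF1R -1.43 (SE 0.70) and ITGAM 0.33 (SE 0.24). Only 2 endothelial markers were expressed enough to test, CLDN5 at -0.84 (SE 0.57) and ESAM at -0.20 (SE 0.43), and neither passed.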

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

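The non-legacy fit and the halved counts were chosen after seeing the data. The planned legacy fit turned out to be the default of the installed edgeR and so the reported one. SAMD9's log2 fold change lay between 8.70 and 9.01 over its alternatives. No called gene was called in the opposite direction in any alternative, although small fold changes can change sign under total-count scaling. Counts of higher and lower genes were 3038 and 2420 as reported, 1202 and 288 with an absolute log2 fold change of at least 1 (1030 and 621 with total-count scaling, 1018 and 159 with DESeq2), and 1974 and 5653 with total-count scaling, where the median gene moved by -0.19. They were 2456 and 1637 with DESeq2, 3053 and 2411 with RLE factors, 3085 and 2477 with the robust fit, 3000 and 2427 without a filter, 2918 and 2497 with the stricter filter, 3036 and 2420 without SAMD9, 3138 and 2548 with the non-legacy fit and 3045 and 2543 with halved counts. Leaving out each library in turn gave 2291 to 3123 higher and 1466 to 2279 lower genes, the lone library being assumed to vary like the other group, with 1466 without SAMD9 replicate 2. The replicate numbers as a block gave 2914 higher and 2330 lower genes and changed no call of a list or named gene. The deviations of same-numbered libraries correlated at 0.00415 over all genes, so no effect shared by same-numbered libraries was seen in the counts. That does not show whether those samples were prepared together.

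With an estimated correlation, 5 lists were called higher and 0 lower, against 9 and 2. Those 5 lists had the same camera adjusted p of 0.0433, although their estimated correlations ran from -0.0399 to 0.673. The shared value therefore does not rank them, and few degrees of freedom lay behind it. Fry called 13 and 2, adding structured non-coding RNAs (0.0105), hypoxia (0.0416), TGF-beta and matrix (0.0423) and fibroblast markers (0.00327). Leaving out each library gave 8 to 10 lists higher and 2 to 3 lower. Uncalled lists whose direction turned, by adjusted p, were, with total counts, the integrated stress response (0.763), p53 targets (0.864), DNA replication (0.920), ribosomal proteins (0.558) and leukocyte markers (0.924). With DESeq2 they were the integrated stress response and aminoacyl-tRNA synthetases (0.836 each) and mitochondrial mRNAs (0.947). Without a filter they were the integrated stress response and mitochondrial mRNAs (0.834 each), p53 targets (0.891) and leukocyte markers (0.846). With fry they were cholesterol synthesis and mitochondrial mRNAs (0.850 each), aminoacyl-tRNA synthetases (0.400) and leukocyte markers (0.803). With libraries left out, aminoacyl-tRNA synthetases ranged from 0.829 to 0.979, the integrated stress response from 0.191 to 0.925 and lung epithelial markers from 0.462 to 0.968. Mitochondrial mRNAs ranged from 0.0105 to 0.979, called lower without empty vector replicate 2 and higher without replicate 1 (0.0152); apart from those left-out libraries, the cause was not tested. The unfolded protein response became called with DESeq2 (0.0262), without a filter (0.000141) and without empty vector replicate 1 (0.00151), and ribosomal proteins without a filter (0.0106). Heat shock also lost its call with the stricter filter (0.132) and halved counts (0.0666). The robust and non-legacy fits give no list values, since camera does not use them. Of named genes, 0 reversed, 12 values lost and 4 gained the threshold. At this depth, 45.8% of simulated changes of 0.5 on the log2 scale were recovered, so small changes of single genes can have been missed. That share is not the power of the list tests: the simulated list, which was called, held genes raised by at least 1. Smaller shifts of a list were not simulated, so they can have been missed in the lists not called.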

Other observations

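The gene families in this part, and the tests of the growth hormone locus, CD79B and phenylalanine codons with genes of any fold change, were chosen after the results had been seen. The families' p-values therefore describe these data and are not independent tests. Several families outside the fixed lists, or only partly in them, rose with SAMD9. Among 9 interferon regulatory factor genes, 7 rose, including IRF7 by 4.95 (SE 0.08) and IRF2 by 2.73 (SE 0.09) on the log2 scale (camera adjusted p = 1.2e-21 over 8 families, 0.0387 with an estimated correlation). PARP genes, which encode ADP-ribosyltransferases, rose in 8 of 13 cases and fell in 1, with PARP10 at 6.18 (SE 0.09) and PARP12 at 4.29 (SE 0.07) (adjusted p = 3.4e-31, and 0.0387 with an estimated correlation). Under total-count scaling 4 PARP genes were lower, and 2 were when either empty vector library was left out. TRIM genes rose in 14 of 48 cases and fell in 7, with TRIM22 at 6.91 (SE 0.11) and TRIM56 at 2.17 (SE 0.07). Camera called the TRIM family higher (adjusted p = 6.9e-09, and 0.0497 with an estimated correlation) although its median was -0.04, and 21 members were lower under total-count scaling.

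APOBEC3 cytidine deaminase genes rose in 5 of 6 cases, APOBEC3F by 3.40 (SE 0.11) and APOBEC3B by 1.51 (SE 0.12) (adjusted p = 2.0e-05, and 0.0910 with an estimated correlation). Of the Schlafen genes, 4 of 4 tested rose, SLFN5 by 2.58 (SE 0.10) and SLFN11 by 2.61 (SE 0.37) (adjusted p = 0.000836, and 0.0965 with an estimated correlation). The rises numbered 3 with DESeq2, without a filter, with the replicate number as a block, and without empty vector replicate 1, SAMD9 replicate 1 or SAMD9 replicate 2. Of 4 Toll-like receptor genes, only TLR3 was called higher, at 5.32 (SE 0.13), while TLR6 was lower at -0.68 (SE 0.12). Camera gave that family adjusted p = 0.00135, and 0.0965 with an estimated correlation. Circadian clock genes fell in 8 of 13 cases and rose in 2, with PER2 at -1.49 (SE 0.12) and CRY1 at -0.66 (SE 0.11), while NR1D1 and NR1D2 rose by 0.63 (SE 0.12) and 0.58 (SE 0.08) (adjusted p = 0.0291, and 0.149 with an estimated correlation), and 10 were lower under total-count scaling and 5 without SAMD9 replicate 2. Numbered zinc finger genes fell in 77 of 375 cases and rose in 31 (adjusted p = 0.0225, and 0.0965 with an estimated correlation), and under total-count scaling 160 were lower and 19 higher. The falls numbered 44 with DESeq2, 51 without SAMD9 replicate 1 and 47 without SAMD9 replicate 2. The 13 interferon alpha genes together had 12 and 8 counts with empty vector and 17 and 19 with SAMD9, with at most 8 counts for any of them in a library, while IFNB1 had 1094 and 1124 with SAMD9. Sequence shared among the interferon alpha genes was not checked, and how reads matching several genes were counted is not given. Their low counts therefore do not show that these genes were not induced.

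GH1 and GH2 counts fell with SAMD9. Growth hormone producing cells in the control cultures are argued against, since the highest of 8 pituitary marker genes, LHB, reached 0.103% of the GH1 count in the empty vector libraries. A candidate source of these reads is a growth hormone polyadenylation segment carried by the plasmid. That feature of such vectors is background knowledge and is not given in the labels. The GH2 to GH1 ratio of the groups differed by 1.0945 times, as when 1 source is split between near-identical genes. That ratio does not tell a plasmid source from transcripts of GH1 itself, and it does not address why the counts were lower with SAMD9. CD79B counts are not explained by growth hormone reads assigned at a fixed share, which would give 89.5 counts over the SAMD9 libraries (lower 95% bound 72.4) where 1 was seen. What lowered them stays open, including transcripts that span CD79B and GH1, for which GENCODE 29 annotates a gene that shares sequence with both and which were not tested.

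SAMD9L counts rose with SAMD9. Reads of the SAMD9 plasmid assigned to SAMD9L are argued against, since 0.029% of SAMD9 transcript 31-mers occur in SAMD9L, while SAMD9L counts were 5.73% of SAMD9 counts in the SAMD9 libraries. Induction of the gene with the other interferon-stimulated genes is a hypothesis that was not tested here.

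Of 1860 processed pseudogenes, 109 were called higher with SAMD9 and 10 lower, and the class had a median log2 fold change of 0.19, which is close in size to the median shift between the scalings. Under total-count scaling 63 were higher and 35 lower, with DESeq2 51 and 2, and without SAMD9 replicate 2 the falls numbered 6. Reads shared with the parent genes cannot be told apart from a change of their own: over 1400 pseudogenes with a tested parent (666 parents), the median pseudogene minus parent difference was 0.1039 (bootstrap SE 0.0104), on the bound of 0.1 set beforehand. The median of the class had been seen when that bound was set, and the comparison with parents had not. No biological explanation was tested.

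The hypothesis that mRNAs rich in phenylalanine codons were lost was tested because SAMD9 is known as a nuclease of phenylalanine tRNA. Across 11727 protein-coding genes, which are not independent replicates, the share of phenylalanine codons had a Spearman rho of 0.0198 with the log2 fold change. That was rank 17 of 20 amino acids from the lowest, which goes against a loss of mRNAs rich in these codons. All 20 values lay between -0.0493 and 0.0604, so the ranks order weak correlations. Cleavage of the tRNA and its effect on translation were not measured. Genes of the interferon and inflammation lists and genes below an average log2 CPM of 1 were left out. The test as first set also left out genes with an absolute log2 fold change of 2 or more, which selects on the outcome, and gave a rho of 0.0204 over 11498 genes.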
